A study of Mus musculus with 6 samples.

How the data were processed

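RNA sequencing was used to measure gene expression in the whole hippocampus of mice carrying a homozygous deletion of exon 4 of Tet1 and of wild-type mice. Tet1 encodes a dioxygenase that oxidises 5-methylcytosine in DNA. Per the labels' protocols, every mouse received electroconvulsive shock through clamps on the ears, at 18 mA and 100 Hz with pulses of 0.2 ms for 1.15 seconds. This stimulus evokes a tonic-clonic seizure. Hippocampi were frozen 1.5 to 2 hours later, RNA was extracted with Trizol, and libraries were sequenced on an Illumina instrument. There were 3 libraries of each genotype, and the design text counts 3 mice per genotype. Replicate numbers are names given here in the order of the samples and pair no libraries. The sample titles carry codes with an f for wild-type replicate 1 and an m for the others, and a further letter that is b for wild-type replicate 3 and a for the others; the labels explain neither. Libraries from unshocked mice were not analysed here, so induction by the shock itself was not measured.

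The authors deposited a table of gene-level FPKM values (fragments per kilobase of transcript, scaled to the mapped total of each library), with 1 column per library. Per the submitters' processing notes, the tools were TopHat2 version 2.0.9 and Cufflinks version 2.1.1, and the genome build was mm10. The gene annotation, the strand setting, the treatment of reads that map to several places and any filter are not given in the sources used here. FPKM divides by transcript length and by the library's mapped total, so read depth cannot be read from it. Low values were compared between libraries to look for steps of whole reads. Among 362 genes under 0.03 FPKM in both wild-type replicate 1 and Tet1-deficient replicate 1, at most 5 had the same ratio to 3 decimals, so the values are fractional estimates and the depth of each library is unknown. No interval or floor that needs a read count is given. The FPKM sums ran from 371014 to 390042 per library and the 75th percentiles from 11.9 to 12.1 FPKM. No pair of libraries had more than 1 nonzero value in common, so no library repeats another.

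The table held 23361 gene symbols, of which 19123 were above 0 in at least 1 library. The 12533 genes with a mean of at least 1 FPKM over the 6 libraries were tested. Values were taken as log2(FPKM + 1), so a log2 difference understates the change of genes near 1 FPKM. The genotype difference was fitted with limma 3.58.1 in R 4.3.3, with an intensity trend and no covariate, as a two-sided moderated test with Benjamini-Hochberg adjustment and a threshold of 0.05. All log2 differences are Tet1-deficient minus wild-type. Means are given ± SD over 3 libraries, and SE is limma's. Tet1 and Gal lay under the 1 FPKM filter, and their log2 differences come from the same model fitted to all genes above 0. An exact two-sided permutation test was run on the Tet1 values and on the library means of each gene list. With 3 libraries against 3 its smallest possible p is 0.1.

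Of 45 gene lists, the 43 with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01. The 43 cover activity-regulated genes, DNA methylation and repair enzymes, synapse and ion channel genes, stress and hormone responses, hippocampal cell types, and tissues that a dissection can bring along. Ribosomal protein, nuclear-encoded oxidative phosphorylation and histone genes were included as lists of quality. A list of mitochondrially encoded genes had 0 members in the table and a list of germline genes had 3 tested members, so neither was tested. Camera with an estimated correlation for each list and fry were run beside the preset test.

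The groups, the tests, the thresholds, the gene lists and most alternatives were fixed before the data were examined. So was the rule for the named genes. It takes Tet1, genes past the threshold with groups that do not overlap (up to 12 rises and 12 falls, without sex-linked genes), and the 10 smallest unadjusted p-values if fewer than 10 genes pass. It adds up to 4 members with the smallest p of each list past the threshold, and 15 genes of activity regulation, DNA methylation and galanin signalling whatever their values. Genes outside the rule are said to be chosen after their values were seen. Not every gene that the rule takes is reported here.

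The alternatives were a pseudocount of 0.1 FPKM, no filter on level, median-of-ratios scaling, quantile normalization, limma without the trend, estimated library weights, a threshold of 0.1, removal of sex-linked genes, and leaving out each library in turn. A principal component analysis later set 2 libraries apart from the other 4. Added after the data were seen were a model with that split as a term, a fit to the 4 libraries alone, and a fit after removal of each library's spline trend (5 degrees of freedom) on transcript GC content and length. GC content, length and gene positions were taken from GENCODE mouse release M21 on GRCm38, the assembly that mm10 names, and 94.2% of tested genes had a value. Transcript copies were searched with blastn 2.17.0 against the longest transcript of each gene.

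The model was tested on simulated data with the means and spreads of these 12533 genes and 200 genes changed by known amounts. It recovered 14.9% of genes changed by 1.5-fold, 59.7% of those changed by 2-fold and 95.5% of those changed by 4-fold, and 3 of its 116 calls were unchanged genes. The Benjamini-Hochberg adjustment becomes less strict as more genes change, and the real comparison called 4 genes. These shares therefore overstate what the real comparison could recover.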

Results

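The series compares the hippocampal transcriptome of Tet1-deficient and wild-type mice after a seizure evoked by electroconvulsive shock. Each genotype was represented by 3 libraries of whole hippocampus, given as gene-level FPKM. Read depth is unknown. The 6 libraries resembled each other closely, with Pearson correlations across genes from 0.965 to 0.990. The mean correlation was 0.975 within genotypes and 0.978 between them.

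Tet1 transcript was scarce in both genotypes. It measured 0.864 ± 0.132 FPKM (SD, n = 3) in wild-type and 0.688 ± 0.0507 FPKM (SD, n = 3) in Tet1-deficient hippocampus, a ratio of 0.796. The wild-type libraries had 0.977, 0.718 and 0.897 FPKM and the Tet1-deficient libraries 0.740, 0.685 and 0.638 FPKM, so the groups overlapped. The log2 difference was −0.14 with an SE of 0.068, and its unadjusted limma p was 0.081. An exact two-sided permutation test gave p = 0.2, where 0.1 is the smallest p possible. Without wild-type replicate 2 the log2 difference was −0.20 and the unadjusted limma p 0.019. Tet1 lies on chromosome 10 from 62804570 to 62908996 (mm10), and a gene-level value over all of its exons does not check the deletion of a single exon. The related dioxygenase genes Tet2 and Tet3 did not pass the threshold. Tet2 measured 8.58 ± 1.19 FPKM in wild-type and 10.3 ± 0.142 FPKM in Tet1-deficient libraries (SD, n = 3), and Tet3 25.4 ± 11.3 and 26.1 ± 6.14 FPKM. The Tet2 values did not overlap between the groups (log2 difference 0.25, unadjusted limma p 0.0638), while those of Tet3 did.

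Few genes passed the threshold for a difference between the genotypes. Ndn, which encodes necdin, a growth-suppressing protein of postmitotic neurons expressed from the paternal allele, fell to 45.0% of its wild-type level. It measured 89.3 ± 4.12 FPKM in wild-type and 40.2 ± 0.191 FPKM in Tet1-deficient hippocampus (SD, n = 3). The predicted genes Gm3893, Gm10406 and Gm3558 rose. Gm3893 went from 0.810 ± 0.161 to 4.81 ± 0.332 FPKM, Gm10406 from 0.657 ± 0.0766 to 3.04 ± 0.139 FPKM, and Gm3558 from 1.09 ± 0.00660 to 3.67 ± 0.159 FPKM (SD, n = 3).

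These 4 genes were the ones of 12533 tested that passed the threshold in limma, each with an adjusted p of 0.00852 and each separated in 3 of 3 libraries against 3. The log2 difference was −1.13 (SE 0.0812) for Ndn, 1.69 (SE 0.105) for Gm3893, 1.29 (SE 0.0888) for Gm10406 and 1.16 (SE 0.0829) for Gm3558. With a pseudocount of 0.1 FPKM the rises of the Gm genes were 2.45, 2.06 and 1.67. Ndn occupies 62346569 to 62350262 on chromosome 7, and its longest transcript covers the locus without an intron. Gm3893 lies at 42091207 to 42092287 on chromosome 4, Gm10406 at 7006115 to 7027449 on chromosome 14 and Gm3558 at 7545151 to 7568566 on chromosome 14. All 4 are annotated as protein-coding. The annotation places Gm32061 on the strand opposite Ndn and Gm17121 on the strand opposite Gm3558, and without strand the reads of such partners cannot be told apart. The transcripts of the Gm genes match 11, 34 and 30 other genes, in the order given, at 95% identity or more over at least 80% of their length, so their values are uncertain. Gm10406 and Gm3558 match each other in this way and can share reads, so their rises need not be separate. Leaving out wild-type replicate 2, wild-type replicate 3, Tet1-deficient replicate 2 or Tet1-deficient replicate 3 ended all 4 calls, with 1, 0, 0 and 1 other genes called. When any 1 library was left out, the log2 difference stayed between −1.15 and −1.09 for Ndn, 1.61 and 1.73 for Gm3893, 1.25 and 1.32 for Gm10406, and 1.14 and 1.18 for Gm3558, and the adjusted p of each reached at most 0.125.

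**Figure D1:**
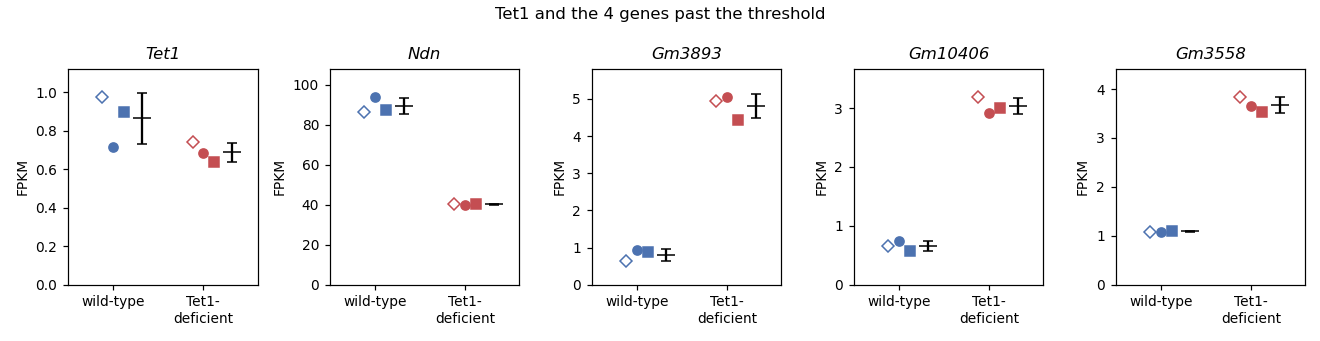
FPKM of Tet1, Ndn, Gm3893, Gm10406 and Gm3558 in each library of wild-type (blue) and Tet1-deficient (red) hippocampus; open diamonds are replicate 1, circles replicate 2 and squares replicate 3, and the black bar gives the mean ± SD of 3 libraries. Tet1 overlaps between genotypes, while Ndn falls from 89.3 to 40.2 FPKM and the 3 Gm genes rise without overlap.

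The next 6 genes by unadjusted p did not pass in the model fixed beforehand, though each passed in at least 1 alternative. D130017N08Rik measured 3.59 ± 0.623 FPKM in wild-type and 0.636 ± 0.307 FPKM in Tet1-deficient libraries (log2 difference −1.50, adjusted p 0.144). Slc38a5, a glutamine transporter gene, had a log2 difference of −0.81 (adjusted p 0.189), Slc26a10, of an anion exchanger family, −1.10 (adjusted p 0.201), and Hhatl −0.72 (adjusted p 0.219). Gm3002 and Gm5796, both among the genes that Gm10406 and Gm3558 match, had log2 differences of 1.20 (adjusted p 0.189) and 1.09 (adjusted p 0.219). In all, 171 genes had an unadjusted p under 0.05, 56 of them higher and 115 lower in Tet1-deficient hippocampus, where 627 would be reached by chance; with the library split as a term there were 848, with library weights 1232 and in the 4 libraries alone 484. The groups did not overlap for 4.13% of tested genes, against 10% by chance. The model found 59 genes with library weights, 8 with the library split as a term and 12 in 4 libraries alone, and each of these sets included the 4 genes above. All 6 of the next genes passed with library weights (adjusted p 0.000306 to 0.00189), Hhatl and Gm5796 with the split as a term (adjusted p 0.0446 and 0.0466), D130017N08Rik and Slc26a10 in the 4 libraries (adjusted p 0.0369 each), Slc26a10 without wild-type replicate 1 (adjusted p 0.0352) and Gm5796 with GC content and length removed (adjusted p 0.0385). The split, the 4 libraries and the GC removal were chosen after the data were seen.

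Immediate early genes, which neurons transcribe within minutes of firing, differed between genotypes in their list mean by less than the spread between replicates. Fos, Egr1 and Arc measured 25.2 ± 12.4, 113 ± 49.3 and 216 ± 7.73 FPKM in wild-type and 24.8 ± 8.59, 108 ± 35.1 and 215 ± 49.2 FPKM in Tet1-deficient hippocampus (SD, n = 3). Npas4, a transcription factor gene induced by calcium entry, measured 8.21 ± 6.35 and 5.58 ± 2.16 FPKM, and Nr4a1 50.7 ± 25 and 45.1 ± 12.9 FPKM. Egr2 measured 5.39 ± 3.88 and 5.40 ± 2.96 FPKM and Egr4 23.2 ± 8.10 and 23.1 ± 6.21 FPKM. Of the 45 listed immediate early genes, 16 were higher and 29 lower in Tet1-deficient libraries and 0 changed, also adjusted over the list alone. Their mean log2 difference was −0.03 (camera adjusted p 0.432, adjusted p 0.848 with an estimated correlation). The sign turned without wild-type replicate 1 (0.13, camera adjusted p 0.0275) and without Tet1-deficient replicate 2 (0.07, adjusted p 0.363), and the camera adjusted p was 0.000767 without wild-type replicate 3 (−0.14). By library, the mean deviation of the list from the gene averages was 0.34, −0.08 and −0.21 in wild-type and 0.10, −0.21 and 0.06 in Tet1-deficient hippocampus, so the spread within genotypes exceeded the difference between them.

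Delayed activity-regulated genes, whose products act at synapses and in signalling, also differed in their list mean by less than the spread between replicates. Bdnf, a neurotrophin gene, measured 50.3 ± 13.5 FPKM in wild-type and 50.2 ± 8.45 FPKM in Tet1-deficient hippocampus, and Homer1, a postsynaptic scaffold gene, 173 ± 30.3 and 196 ± 35.2 FPKM (SD, n = 3). Of 29 tested members, 19 were higher and 10 lower and 0 changed, also adjusted over the list alone. The mean log2 difference was 0.03 (camera adjusted p 0.516, adjusted p 0.636 with an estimated correlation), and it was −0.0028 without wild-type replicate 1. Gadd45b, an activity-induced gene tied to DNA demethylation, measured 32.5 ± 5.61 and 33.6 ± 9.46 FPKM. The neuropeptide gene Gal had 1.23 ± 0.455 FPKM in wild-type and 0.430 ± 0.161 FPKM in Tet1-deficient libraries (SD, n = 3), a ratio of 0.350 without overlap between the groups. Its log2 difference was −0.63, with an unadjusted limma p of 0.00629 and an adjusted p of 1.00.

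**Figure D2:**
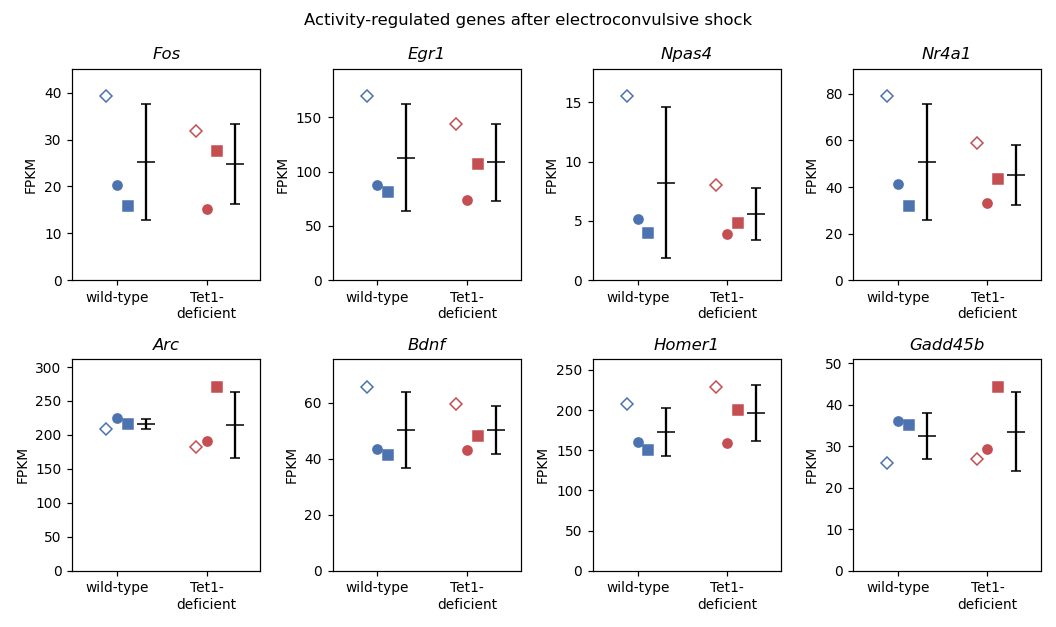
FPKM of activity-regulated genes in each library of wild-type (blue) and Tet1-deficient (red) hippocampus; open diamonds are replicate 1, circles replicate 2 and squares replicate 3, and the black bar gives the mean ± SD of 3 libraries. The genotypes overlap for all 8 genes, and wild-type replicate 1 has the highest value of Fos, Egr1, Npas4, Nr4a1 and Bdnf.

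No shift of the DNA methylation machinery passed the test. Of its 19 tested genes 0 changed, also adjusted over the list alone, with a mean log2 difference of 0.03 (camera adjusted p 0.546, adjusted p 0.674 with an estimated correlation). The maintenance methyltransferase gene Dnmt1 measured 12.8 ± 1.55 FPKM in wild-type and 11.5 ± 2.5 FPKM in Tet1-deficient hippocampus, and Dnmt3a 11.2 ± 1.30 and 11.2 ± 1.49 FPKM (SD, n = 3). The 43 tested genes listed around Tet1 on chromosome 10 had a mean log2 difference of 0.01 (camera adjusted p 0.493). Among the 78 tested genes within 10 Mb of Tet1, 0 had an unadjusted p under 0.05, against 171 of 12455 elsewhere (Fisher's exact test, two-sided p = 0.629).

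Of the 43 gene lists, 12 passed camera at the preset correlation, 6 higher and 6 lower in Tet1-deficient hippocampus. With an estimated correlation 0 lists passed, and the adjusted p of these 12 lay between 0.332 and 0.570. With fry 0 passed, and their adjusted p lay between 0.664 and 0.883. The directions below therefore describe the measured values of the lists and do not hold against the correlation between their members. The 31 other lists, among them synaptic vesicle, glutamate receptor, ion channel, astrocyte, oligodendrocyte and dentate granule cell genes, had camera adjusted p-values from 0.0545 to 0.936.

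Markers of vessel and membrane cells made up the largest list shifts toward lower values. All 12 tested genes of meningeal fibroblasts were lower in Tet1-deficient hippocampus, with a mean log2 difference of −0.57 (camera adjusted p 2.32e-07, adjusted p 0.460 with an estimated correlation). The collagen genes Col1a1 and Col3a1 measured 4.32 ± 2.63 and 2.1 ± 1.32 FPKM in wild-type and 2.19 ± 0.736 and 0.984 ± 0.427 FPKM in Tet1-deficient libraries (SD, n = 3). Of 10 genes of pericytes and smooth muscle 8 were lower (mean −0.27, adjusted p 0.485 with an estimated correlation), as were 15 of 16 endothelial genes (mean −0.20, adjusted p 0.570 with an estimated correlation). Tagln, of smooth muscle, measured 3.47 ± 1.55 and 1.84 ± 0.449 FPKM, and Cldn5, of endothelial tight junctions, 6.18 ± 2.35 and 4.44 ± 1.96 FPKM. The fibroblast list lost its camera call without wild-type replicate 1 (mean −0.37, adjusted p 0.0863) and the pericyte list without Tet1-deficient replicate 1 (mean −0.21, adjusted p 0.106). The endothelial list lost its call without either of these (means −0.18 and −0.14, adjusted p 0.171 and 0.0571). It also lost the call without replicate 3 of wild-type or Tet1-deficient hippocampus (means −0.06 and −0.07, adjusted p 0.213 and 0.491). With 1 library left out the mean ran from −1.03 (without wild-type replicate 2) to −0.31 (without wild-type replicate 3) for fibroblasts, from −0.41 to −0.13 (without the same libraries) for pericytes, and from −0.39 (without Tet1-deficient replicate 2) to −0.06 (without wild-type replicate 3) for endothelial cells. In the 4 libraries that lie together on the first principal component, a choice made after the data were seen, the pericyte and endothelial calls were lost, with means of −0.21 (adjusted p 0.143) and −0.12 (adjusted p 0.334). The exact permutation p of the 3 lists' library means was 0.3, 0.2 and 0.4, where 0.1 is the smallest possible.

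Among lists of neurons and their precursors 3 were lower. Of 18 genes of immature neurons and neurogenesis 13 were lower (mean −0.10, adjusted p 0.332 with an estimated correlation), and Hes5, a Notch effector gene, fell when adjusted over the list alone (4.02 ± 0.142 to 2.55 ± 0.236 FPKM, SD, n = 3, adjusted p 0.0174) but not over all genes (adjusted p 0.576), where it passed with library weights alone (log2 difference −0.50, adjusted p 0.00936). Among CA1 pyramidal markers 9 of 10 were lower (mean −0.17, adjusted p 0.332 with an estimated correlation), and among GABAergic interneuron markers 16 of 19 (mean −0.10, adjusted p 0.485 with an estimated correlation). The CA1 marker Spink8, with a log2 difference of −0.72, weighed heavily on its list mean. It measured 16.1 ± 9.46 and 8.55 ± 3.28 FPKM (SD, n = 3), and its libraries overlapped between genotypes. Dcn belongs to both the CA1 and the meningeal fibroblast list, and Calb2 is listed under both immature neurons and interneurons, so these lists are not separate. Sst, the somatostatin gene, measured 282 ± 57.0 FPKM in wild-type and 217 ± 66.9 FPKM in Tet1-deficient hippocampus (SD, n = 3), and Gad1 108 ± 0.672 and 99.1 ± 6.91 FPKM. The camera call of immature neurons was lost without wild-type replicate 1, where the mean was −0.13 (adjusted p 0.0606), and without Tet1-deficient replicate 1 (adjusted p 0.176), that of CA1 cells without wild-type or Tet1-deficient replicate 2 (adjusted p 0.0642 and 0.256), and that of interneurons without wild-type replicate 2 or Tet1-deficient replicate 1 (adjusted p 0.224 and 0.426). With 1 library left out the mean ran from −0.14 (without Tet1-deficient replicate 2) to −0.05 (without Tet1-deficient replicate 1) for immature neurons, from −0.21 (without Tet1-deficient replicate 1) to −0.10 (without Tet1-deficient replicate 2) for CA1 cells and from −0.17 (without Tet1-deficient replicate 2) to −0.03 (without Tet1-deficient replicate 1) for interneurons. With GC content and length removed the CA1 mean was −0.16, close to the −0.17 before, though its adjusted p was 0.0561. The exact permutation p of the library means was 0.2 for immature neurons, 0.1 for CA1 cells and 0.5 for interneurons. The other lists of hippocampal neurons were not called: 6 of 7 CA2 markers were higher (mean 0.07, camera adjusted p 0.0612), 9 of 14 dentate granule cell markers (mean 0.03, adjusted p 0.603), 7 of 10 CA3 markers (mean 0.0049, adjusted p 0.603) and 2 of 6 mossy cell markers (mean −0.03, adjusted p 0.603). In the 4 libraries the dentate granule cell list passed camera with a mean of 0.14 (adjusted p 0.000623). With an estimated correlation its adjusted p was 0.848 in all libraries, and that test was not run on the 4. Ribosomal protein (mean −0.05, camera adjusted p 1.28e-05), oligodendrocyte (0.06), oligodendrocyte precursor (0.08) and neuropeptide genes (−0.09, adjusted p 0.0458 each) also passed there but not in all libraries. Some fits with 1 library left out called further lists too, and their names are not given here. In all libraries the means of the first 3 had the opposite sign (0.02, −0.04 and −0.02).

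Protein-folding and stress genes lay higher. Of 21 genes of the unfolded protein and Atf4 response 16 were higher in Tet1-deficient hippocampus (mean 0.15, camera adjusted p 2.37e-06, adjusted p 0.332 with an estimated correlation). The endoplasmic reticulum chaperone genes Hspa5 and Hsp90b1 measured 161 ± 10.9 and 121 ± 4.19 FPKM in wild-type and 217 ± 28.8 and 152 ± 18.9 FPKM in Tet1-deficient libraries (SD, n = 3), and the transcription factor gene Xbp1 21.9 ± 1.00 and 27.1 ± 1.47 FPKM. These 3 genes did not overlap between genotypes, and none passed the threshold. Of 18 glucocorticoid-responsive genes 17 were higher (mean 0.13, adjusted p 0.332 with an estimated correlation), with Mt2, a metallothionein gene, at 376 ± 23.6 and 474 ± 35.7 FPKM. Of 18 heat shock genes 15 were higher (mean 0.07, adjusted p 0.332 with an estimated correlation), as were all 5 tested inflammatory genes (mean 0.22, adjusted p 0.332 with an estimated correlation), such as Serpina3n at 30.0 ± 3.99 and 46.3 ± 20.2 FPKM. Serpina3n, with a log2 difference of 0.53, weighed heavily on the inflammatory mean. Its Tet1-deficient libraries measured 32.9, 36.4 and 69.4 FPKM and overlapped the wild-type ones, at 25.8 to 33.6 FPKM. The heat shock gene Hspb8 fell without overlap, from 3.12 ± 0.544 to 2.06 ± 0.239 FPKM (SD, n = 3, unadjusted limma p 0.0131). It was the only member of its list with an unadjusted p under 0.05. Histone genes were higher in 13 of 14 tested of 68 listed (mean 0.21, 0.07 with no filter on level, adjusted p 0.332 with an estimated correlation) and nuclear-encoded oxidative phosphorylation genes in 65 of 87 (mean 0.05, adjusted p 0.570 with an estimated correlation). The histone and oxidative phosphorylation lists were fixed as lists of quality, not of stress. Nfkbia is listed under both glucocorticoid-responsive and inflammatory genes, and Ddit4 under both glucocorticoid-responsive and unfolded protein genes, so these lists are not separate. Across these 6 lists 0 members changed, also adjusted over the list alone. The camera call was lost for heat shock genes without replicate 1 or 2 of either genotype (adjusted p 0.0983 to 0.256), for inflammatory genes without wild-type replicate 1 or 2 or Tet1-deficient replicate 3 (adjusted p 0.0845 to 0.105), and for oxidative phosphorylation without replicate 1 of wild-type or Tet1-deficient hippocampus (adjusted p 0.430 and 0.375). The heat shock mean in these fits was 0.05 and 0.09 without wild-type replicates 1 and 2. Without Tet1-deficient replicates 1 and 2 it was 0.09 and 0.04. The inflammatory mean was 0.24 and 0.20 without wild-type replicates 1 and 2. In the 4 libraries that lie together on the first principal component the mean of the oxidative phosphorylation genes was −0.0056. Among settings that kept all libraries, the call was lost for heat shock genes with library weights and with quantile normalization (adjusted p 0.186 and 0.362), for oxidative phosphorylation with library weights (adjusted p 0.186), and for inflammatory genes with no filter on level, where the mean was 0.04 (adjusted p 0.438), and with the split as a term, where it stayed 0.22 (adjusted p 0.0561). With 1 library left out the mean of the glucocorticoid-responsive genes ran from 0.07 (without wild-type replicate 1) to 0.20 (without wild-type replicate 2), that of heat shock genes from 0.04 (without Tet1-deficient replicate 2) to 0.09 (without Tet1-deficient replicate 1), that of inflammatory genes from 0.15 (without Tet1-deficient replicate 3) to 0.28 (without Tet1-deficient replicate 2), and that of oxidative phosphorylation genes from 0.02 (without wild-type replicate 1) to 0.09 (without Tet1-deficient replicate 2). For the unfolded protein list it ran from 0.10 (without Tet1-deficient replicate 2) to 0.19 (without Tet1-deficient replicate 1) and for histone genes from 0.14 (without wild-type replicate 1) to 0.32 (without wild-type replicate 3). The exact permutation p of the library means was 0.1 for the unfolded protein, heat shock and inflammatory lists, 0.2 for glucocorticoid-responsive, 0.3 for histone and 0.4 for oxidative phosphorylation genes.

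Libraries differed in ways that genotype does not describe. The first principal component held 53.3% of the variance and set wild-type replicate 1 and Tet1-deficient replicate 1, at 26.7 and 27.9, apart from the other 4 libraries, at −15.5 to −10.5. Within the 4 the log2 difference of Ndn was −1.16, and between the 2 it was −1.08. For Gm3893 these values were 1.59 and 1.87, for Gm10406 1.26 and 1.34, and for Gm3558 1.13 and 1.22. Xist, the RNA that coats the inactive X chromosome of females, measured 63.5 FPKM in wild-type replicate 1 and 0.0389 to 0.202 FPKM in the other 5 libraries, and Ddx3y, on the Y chromosome, 0.0381 FPKM there and 16.7 to 35.2 FPKM in the others. By these transcripts wild-type replicate 1 came from a female and the other 5 libraries from males. Sex was therefore not balanced between the genotypes. The fit without wild-type replicate 1, which compared males only, kept the 4 gene calls but only 6 of the 12 list calls by camera. That library also stands apart on the first component, so an effect of sex cannot be told apart from its other traits. Ttr, an abundant transcript of choroid plexus, ran from 3.44 to 294 FPKM among wild-type and from 5.85 to 187 FPKM among Tet1-deficient libraries. The 5 tested choroid plexus genes had a mean log2 difference of 0.06 (camera adjusted p 0.882).

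**Figure D3:**
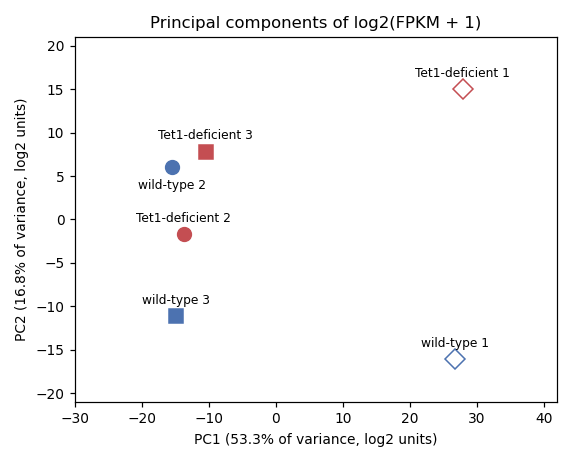
Scores of the 6 libraries on the first 2 principal components of log2(FPKM + 1) over the tested genes, in log2 units, for wild-type (blue) and Tet1-deficient (red) hippocampus, with open diamonds for replicate 1, circles for replicate 2 and squares for replicate 3. The first component (53.3% of the variance) sets 1 library of each genotype apart at 26.7 and 27.9, and the others lie at −15.5 to −10.5.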

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

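The fits with the library split, with 4 libraries alone and with GC content and length removed were chosen only after the data were seen. Ndn, Gm3893, Gm10406 and Gm3558 passed together in 12 of 16 settings of the limma test, and in 4 none of them passed: without wild-type replicate 2 or 3, or without Tet1-deficient replicate 2 or 3. Their adjusted p reached at most 0.125 in any setting, without wild-type replicate 3. All 4 passed without replicate 1 of either genotype and in 4 libraries alone. Those fits also left out libraries that stand apart on the first principal component, which can lower the spread. They therefore cannot tell whether fewer libraries account for the loss. Leaving out 1 library gave 0 to 6 genes. Library weights gave 59 genes, 16 higher and 43 lower against 3 and 1, the split as a term 8 and 4 libraries alone 12; the weights were 0.178, 2.99 and 1.57 in wild-type and 0.176, 0.988 and 6.89 in Tet1-deficient replicates 1 to 3, so Tet1-deficient replicate 3 carries most of that fit, and the cause was not otherwise tested. The number of lists was 0 with an estimated correlation and 0 with fry, and 6 (without Tet1-deficient replicate 1) to 20 (without wild-type replicate 3) with 1 library left out. At the preset correlation the unfolded protein, glucocorticoid-responsive and histone lists passed in all 16 other settings, with means from 0.097 to 0.19, 0.065 to 0.20 and 0.067 to 0.32. The mean log2 difference of immediate early genes ran from −0.14 to 0.13 with 1 library left out and was 0.074 in 4 libraries alone; that of delayed effectors ran from −0.0028 to 0.065, and that of Tet1 from −0.20 to −0.10.

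Among 781 values of named genes in settings other than leaving out 1 library, 754 kept their direction and side of the threshold, 12 passed it in addition, 0 lost it and 15 changed sign, none of these past the threshold. With library weights these were Arc 0.22, Egr1 0.24, Nr4a1 0.13 and Tet3 −0.30. In 4 libraries alone they were Arc 0.051, Egr1 0.079, Nr4a1 0.065, Tet3 −0.18 and Dnmt3a 0.0072. With GC and length removed they were Egr1 0.0097, Egr4 −0.0033, Bdnf −0.032 and Dnmt3a 0.038. Quantile normalization gave Egr4 −0.0053 and median-of-ratios scaling Dnmt3a 0.0069. The cause was not tested. In some of the settings counted among the 781 values the log2 difference of a gene could not change. These were no filter on level, limma without the trend, a threshold of 0.1, removal of sex-linked genes and the split as a term. With 1 library left out, 13 genes changed sign in at least 1 fit. Their log2 differences ran from −0.25 to 0.38 (Fos), −0.21 to 0.076 (Arc), −0.25 to 0.31 (Egr1), −0.28 to 0.52 (Egr2), −0.21 to 0.26 (Egr4), −0.66 to 0.20 (Npas4), −0.37 to 0.27 (Nr4a1), −0.11 to 0.22 (Bdnf), −0.19 to 0.16 (Gadd45b), −0.30 to 0.35 (Tet3), −0.25 to 0.026 (Dnmt1), −0.092 to 0.083 (Dnmt3a) and −0.10 to 0.54 (Ccl2). No paired analysis was possible because the codes in the sample titles share just 1 number between the groups, and the replicate numbers used here only follow the order of the samples. Depth is unknown from FPKM, so its limits could not be set.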

Other observations

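Chosen only after the results were seen were the fry test of change in either direction, the split counts of protocadherins, the tests of Xist, of genes listed on one side of the library split and of chromosome 10, and genes outside the naming rule. The library split was itself found from these data, so every test that uses it, that of immediate early genes included, came after the split was seen. Clustered protocadherins, cell-surface proteins whose isoforms are chosen by alternative promoters, differed in both directions. Of 52 tested members 23 were higher and 29 lower, and the list's mean log2 difference was −0.04 (camera adjusted p 0.252). The fry test of change in either direction gave an adjusted p of 2.37e-05, and its unadjusted p was at most 0.00855 with any 1 library left out. Adjusted over the list alone 3 members changed: Pcdhgb4 rose from 3.33 ± 0.179 to 5.67 ± 0.817 FPKM, Pcdhga6 fell from 3.58 ± 0.286 to 2.21 ± 0.173 FPKM and Pcdhga3 fell from 5.15 ± 0.279 to 3.04 ± 0.684 FPKM (SD, n = 3), and over all genes 0 did. Unadjusted p-values under 0.05 were found for 4 of 10 alpha, 0 of 20 beta and 6 of 22 gamma members. All alpha and all gamma gene models end within 1 kb of a shared 3' end, so division of their reads between members is uncertain. Among the 10 splits of the 6 libraries into 3 and 3, 1 split, the real one, gave 10 such protocadherins, and the highest other gave 7; these splits are too few for a share under 0.05.

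Among imprinted genes the test rested on Ndn. The list's fry test of change in either direction gave an adjusted p of 1.17e-05, and without Ndn its unadjusted p was 0.413. Among neighbours of Ndn on chromosome 7, Magel2 measured 1.00 FPKM in wild-type and 1.19 FPKM in Tet1-deficient hippocampus, Snrpn 454 and 540 FPKM, Ube3a 16.9 and 18.7 FPKM, and Snurf 95.4 and 51.1 FPKM, and none passed the threshold. Snurf had a log2 difference of −0.63, like Ndn lower in Tet1-deficient hippocampus, but its libraries ran from 27.1 to 202 FPKM in wild-type and from 28.5 to 94.6 FPKM in Tet1-deficient hippocampus. Fcrls, a microglial receptor gene, fell from 6.44 ± 0.863 to 3.46 ± 0.775 FPKM (SD, n = 3) when adjusted over the microglia list alone (adjusted p 0.0338), not over all genes (adjusted p 0.841). With the split as a term Nrsn2, a neuronal vesicle gene, passed with a log2 difference of −0.72 (adjusted p 0.00399, 0.540 without the term). Snhg1 passed in the same fit with a log2 difference of 0.45 (adjusted p 0.0446, 0.989 without the term).

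The 4 genes past the threshold and the 12 lists were set against the other splits of the 6 libraries. Of 10 splits 1, the real one, gave 4 genes and the highest other gave 0. As many as 12 lists came from 5 splits, and the highest other gave 15. These splits are too few for a share under 0.05. Splits that put wild-type replicate 1 and Tet1-deficient replicate 1 together gave up to 3144 genes with an unadjusted p under 0.05, against 171 for the genotypes, which points to a structure of the libraries.

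That structure set 1 library of each genotype apart. Sex of the animals is argued against, since Xist was high in wild-type replicate 1 and at 0.0910 FPKM in Tet1-deficient replicate 1. GC content may account for part of it: across genes, which are not independent replicates, the loading of the first component had a Spearman's rho of −0.727 with transcript GC content and 0.121 with transcript length, but removing each library's GC trend left 59.7% of the component's variance with the same libraries apart, so neither is the whole cause as measured here, and what share they have stays open because the longest transcript of each gene stands for all its transcripts. A difference in library preparation or quantification is a candidate explanation. On one side 4 genes (Oaz1-ps, Snora15, Snora52 and Snora74a) were over 1 FPKM and on the other at 0, where the other 14 pairs of libraries gave at most 2. The pair was picked from these same values, so the count cannot tell this explanation from others. The labels name no batch, and no biological explanation other than sex was tested.

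The 44 immediate early genes with a GC content and length value were higher in the 2 libraries apart than in the other 4 by a mean log2 of 0.33, most of it from wild-type replicate 1: the mean deviations were 0.33 there, 0.10 in Tet1-deficient replicate 1, 0.07 in Tet1-deficient replicate 3 and −0.21 to −0.08 in the others. GC content and transcript length are argued against, since after their removal 144% of the excess was left. A general shift of genes of like level, GC content and length is argued against too, since the median of 10000 matched random lists was −0.14. The excess lay at percentile 100 of these lists. Immediate early genes vary together (estimated correlation 0.24), which random lists need not, so this percentile gives no measure of chance. After removal of the GC content and length trends the mean deviations were 0.42 in wild-type replicate 1, 0.21 and 0.02 in Tet1-deficient replicates 1 and 3, and −0.26 to −0.13 in the others. The strength of the seizure and the time of harvest within the stated window may also differ between animals, and these were not tested.

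The Gm genes that rose have close copies. Reads shared between near-identical copies are a candidate explanation, since all 3 transcripts match other genes at 95% identity or more, so a rise of a copy may be counted under these names. DNA linked to the Tet1 locus is argued against as the source, since 0 of the 3 and of the 46 genes they match, Gm10406 and Gm3558 among them, lie on chromosome 10 in the reference, though copies that the reference lacks were not searched. A strain variant elsewhere in the genome was not tested and stays open beside an effect of the genotype.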
